A study of Mus musculus with 2 samples.

How the data were processed

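The data are 2 mouse libraries, replicate 1 and replicate 2 of a single group. Per the labels' protocols, embryos were dated at embryonic day 12 (E12), a time of neurogenesis, with EdU, a thymidine analogue that is built into newly made DNA. Animals were killed at postnatal day 3 (P3), the pallial region of the brain was dissected and pooled, and dissociated cells were passed through strainers of 40 and 50 µm. PI-negative, EdU-positive cells among the brightest 10% were sorted and captured in droplets with the 10x Genomics Single Cell 3' chemistry, which counts transcripts by unique molecular identifiers (UMIs) near their 3' ends. Per the file headers, the deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 6.0.2 and kept as matrices of called cells. The submitters' processing notes name mm10, R 4.1.0 and Seurat 4.1.0 with no role, and the annotation release is not given in the sources used here. Nothing in the labels says whether the libraries come from separate pools of animals, so p-values measure only the spread between these samples, which may be technical.

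The files held 32285 genes, 13858 barcodes with 97091962 UMIs in replicate 1 and 14513 barcodes with 108903409 UMIs in replicate 2. Barcodes with fewer than 500 detected genes (441 and 657) and then those with over 10% mitochondrial UMIs (2189 and 2891) were removed. Scrublet, as run in scanpy 1.11.5 per library with an expected doublet rate of 10%, then marked 863 (7.69%) and 821 (7.49%) barcodes as doublets, which were removed. This left 10365 and 10144 cells, or 74.8% and 69.9% of the barcodes. A class with 0 cells would have had an upper limit of 0.0289% of the cells in replicate 1 and 0.0296% in replicate 2, from 3 counts. Shares of single libraries carry exact Clopper-Pearson 95% intervals. These intervals and limits cover counting error only.

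Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen per library and combined gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1.0. Gene list members, mitochondrial, ribosomal protein, hemoglobin and sex-linked genes were kept out of the variable genes. The 28 clusters were compared with 28 marker lists, and clusters of glutamatergic and of GABAergic cells were clustered again at resolution 0.6, a step chosen after the data had been seen, for 40 clusters in the end. A cluster took the name of a list, written as "-like", where its leading genes and at least 3 detected markers spoke for it. It stayed unnamed where they did not, or where its median UMI count was more than 3 times below that of its library and none of the list's markers were among its 10 leading genes by fold. Some clusters with enough markers were left unnamed as well, so the named shares leave them out. Among them were 169 cells with 5 of 6 olfactory bulb neuroblast markers over 2-fold, Pbx3 and Tshz1 among their leading genes. Clusters of 33 and 53 cells had 5 of 6 markers of glutamatergic neurons over 2-fold. The names are rebuilt from markers and can differ from those of the study's authors. Shares of cells with several markers and genes per cell were compared after each cell was thinned to 2000 UMIs, leaving out shallower cells, since the share of cells with a UMI depends on depth. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, igraph 0.11.9 and matplotlib 3.10.9 were used.

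Cells are not replicates, so raw counts were summed per library and class, and classes with at least 20 cells in both libraries entered the model. Sums were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment at 0.05. The library was a block, because both sums of a library come from the same sorted cells. The planned contrasts that were run were GABAergic against glutamatergic cells and astroglia against glutamatergic cells, in a model of 18 sums with 8 residual degrees of freedom, and MGE-derived against CGE-derived interneurons (from the medial and caudal ganglionic eminences), in a model of 34 sums with 16. The planned contrast of deep-layer against upper-layer neurons was not run, because no cluster was named as a deep-layer class. OPC-like against astroglia-like cells was added after the data had been seen. Classes come from clustering the same cells, so the 4239 genes used as variable genes or preset markers were left out of the counts of called genes. Other leading genes of clusters, which also spoke for names, stayed in. Among them were Sema3c, Nrp1, Grm3, Gria1, Syt1, Zbtb16, St18, Pllp and Hspb8, whose tests are not independent of the naming. The SE of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM, the UMIs of a gene scaled to the total UMIs of a class, as mean ± SD of the 2 libraries. A fold against a class with 0 UMIs is a lower bound computed against 3 counts over both libraries, and with 1 to 3 UMIs the ratio is given with its counting interval. Reads of overlapping or antisense genes, and of near-identical gene copies, may have been divided by the counting, and the use of strand in counting is not stated in the sources used here. Genes named for a contrast are called uncertain where their exons overlap those of another counted gene in the annotation used for coordinates.

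The 16 gene lists held axon guidance receptors and ligands, cadherins, glutamate receptors, GABA receptors and chloride transporters, voltage-gated channels, synaptic vesicle release machinery, postsynaptic scaffold and kinases, neurofilaments and cytoskeleton, immature or migrating neuron genes, S phase genes, p53 response genes, immediate early and dissociation stress genes, cholesterol synthesis, glycolysis, nuclear oxidative phosphorylation genes, and Notch and Wnt pathway genes. They were tested with camera (limma 3.58.1), which compares the genes of a list with all other genes, 2-sided, with an inter-gene correlation preset at 0.01 and again with an estimated correlation. Genes were named by a rule: from each list the called members with the largest fold changes, up to 2 in each direction, and outside the lists the 5 called genes with the largest fold changes in each direction, with at least 20 CPM in the higher class, the same direction in both libraries and no unnamed gene models. Between the libraries, genes of at least 50 CPM in either one with a ratio of at least 2 were named. Only some of the genes the rule takes are printed, and a few results are not reported here. Genes were chosen after their values were seen where the text says so.

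The grouping, filters, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, no replicate block, only the classes of a contrast in the model, doublet calls kept, at least 1000 genes, at most 5% mitochondrial UMIs, Leiden resolutions of 0.5 and 2.0, naming each cell alone, leaving out each library, and counting the genes used for clustering. A further alternative assigned each UMI at random to 1 of 2 parts, with classes from 1 part and tests on the other. Added after the data had been seen were cells of at least 3000 UMIs, no limit on mitochondrial UMIs, dividing GABAergic cells counted as GABAergic, and GABAergic cells without the GABAergic neuron-like class.

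The tests were run on simulated data with a known set of changed genes, drawn from the real means and library sizes. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 47.8%, 64.2% and 78.8% of changed genes in the GABAergic contrast (14365 genes), and for 52.2%, 75.4% and 89.4% in the astroglial contrast (14269 genes). In the interneuron contrast (12904 genes) recovery was 7.46%, 25.4% and 59.1%, and in the OPC contrast (12940 genes) 74.6%, 81.8% and 92.3%. False calls made up 4.51%, 2.72%, 4.69% and 2.38% of the calls in these 4 simulations. Each simulation changed 65 to 67 genes at each size, few beside the 744 to 7917 genes called in the real contrasts. Recovery and false calls may therefore differ in the real contrasts. Coordinates are those of mm10 (GRCm38) in the GENCODE vM21 annotation, counted from 1, whose release can differ from the one used to make the counts.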

Results

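The series profiled single cells of the mouse pallium, the dorsal part of the forebrain that includes the cerebral cortex, at P3. Cells were sorted for the strongest EdU label after a dating step at E12, and only the brightest were kept. All cells belong to 1 group with 2 libraries, and the design holds no treatment or control. Comparisons were therefore made between the classes of cells found inside the same libraries, and between the libraries themselves. After filtering, replicate 1 held 10365 cells with a median of 7273 UMIs and 2913 genes per cell, and replicate 2 held 10144 cells with a median of 8281.5 UMIs and 3229.5 genes. The median share of mitochondrial UMIs was 2.95% and 3.28%. The sort for EdU and viability sets which cells could be seen, so the shares below are shares of sorted cells, not of the pallium.

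Cells of the oligodendrocyte lineage made up the largest family, at 38.2% ± 1.13 of the cells (SD, n = 2), and most of them resembled oligodendrocyte precursor cells (OPCs). OPC-like cells alone accounted for 32.5% ± 0.736, dividing OPC-like cells for 4.96% ± 0.296 and oligodendrocyte-like cells for 0.771% ± 0.0945. Astroglia made up 16.6% ± 0.735, glutamatergic neurons 12.1% ± 0.699 and GABAergic neurons 9.16% ± 0.467. The astroglial share leaves out an unnamed cluster of 1290 cells with low UMI counts, in which 7 of 10 astroglial markers were over 2-fold. A cluster of 1359 OPC-like cells with low UMI counts was named and is counted, so these shares are not treated alike. When each cell was named alone by its highest marker score, glutamatergic neurons took 19.8%, above astroglia (16.9%), and GABAergic neurons 14.1%. That rule sums several lists for each of these neuron families and uses a single list for astroglia. The general glutamatergic list alone took 7.43%. Within the GABAergic family, olfactory bulb neuroblast-like cells were most frequent (5.48% ± 0.303), followed by CGE interneuron-like (1.58% in replicate 1 and 1.42% in replicate 2), GABAergic neuron-like (1.01% ± 0.029), MGE interneuron-like (0.780% ± 0.057) and striatal projection neuron-like cells (0.390% ± 0.0216). Dividing GABAergic cells, counted apart, made up 3.72% ± 0.195 and other dividing cells 4.41% ± 0.312. Intermediate progenitors reached 1.06% ± 0.078, Cajal-Retzius cells 0.859% ± 0.137, microglia and macrophages 1.45% ± 0.167, and vascular cells and fibroblasts 0.190% ± 0.037. A cluster of 40 cells with all 7 endothelial markers at least 2-fold up, led by hemoglobin genes and Cldn5, stayed unnamed and is not part of that vascular share. These smaller shares moved by more than their SD between some settings, with ranges of 1.00% to 2.54% for intermediate progenitors, 0.0897% to 2.95% for vascular cells and fibroblasts, and 3.63% to 9.90% for other dividing cells. Clusters without a name held 12.3% ± 0.998 of the cells, with a median of 2505 UMIs.

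The replicates gave close shares for the large families. The oligodendrocyte lineage took 37.4% in replicate 1 (95% interval 36.5% to 38.3%) and 39.0% in replicate 2 (38.0% to 39.9%). Astroglia took 16.1% and 17.1%, glutamatergic neurons 12.6% and 11.6%, and GABAergic neurons 9.49% and 8.83%. The upper-layer neuron-like class was uneven, with 0.675% (0.527% to 0.853%) in replicate 1 and 0.384% (0.274% to 0.525%) in replicate 2. With 2 libraries of 1 group, shares were compared as values and not tested.

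**Figure D1:**
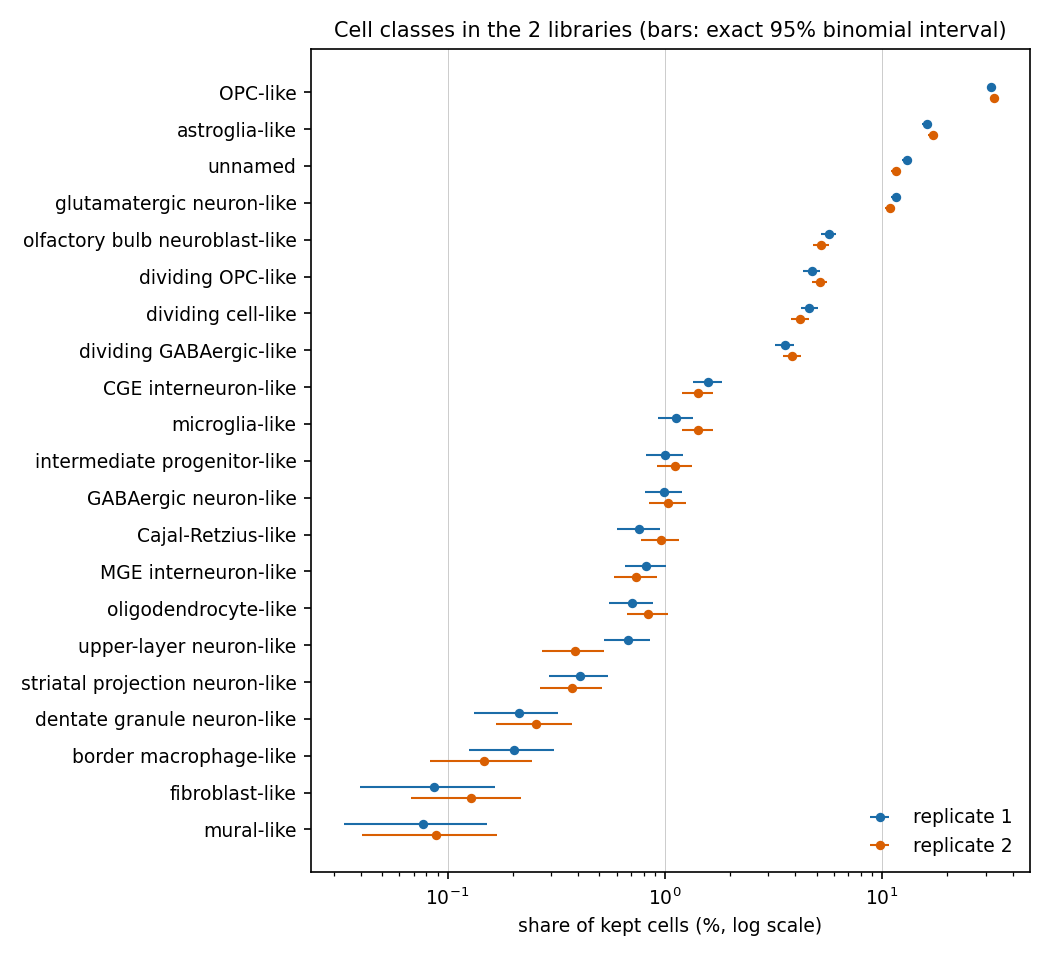
Share of the kept cells in each of 21 classes (percent, log axis), with 1 point per replicate and exact 95% binomial intervals as error bars. OPC-like cells lead with a mean of 32.5%, and the points of both replicates lie close together in the large classes.

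Class names rest on marker levels that differed by large factors between classes, given here as the basis of the names and not as findings. Pdgfra, the PDGF receptor of OPCs, stood at 1011 ± 47.6 CPM in OPC-like cells and 17.8 ± 0.605 CPM in glutamatergic neuron-like cells (mean ± SD, n = 2 here and below), and Cspg4, which encodes NG2, at 407 ± 13.1 and 6.34 ± 1.79 CPM. Aqp4, the water channel of astrocytes, reached 502 ± 15.9 CPM in astroglia-like cells against 15.9 ± 3.90 CPM in glutamatergic neuron-like cells. Neurod2, a transcription factor of glutamatergic neurons, reached 657 ± 47.9 CPM in glutamatergic neuron-like cells against 8.29 ± 0.378 CPM in OPC-like cells. Gad2, a GABA-synthesizing enzyme, was at 660 ± 49.4 CPM in olfactory bulb neuroblast-like cells, and Sp8, a transcription factor of such neuroblasts, at 312 ± 16.0 CPM. Sst, the neuropeptide somatostatin, was at 6139 ± 74.0 CPM in MGE interneuron-like cells and 11.2 ± 0.831 CPM in CGE interneuron-like cells, while Adarb2 stood at 8.90 ± 3.27 and 897 ± 49.2 CPM. Reln, the secreted protein of Cajal-Retzius cells, reached 3685 ± 275.8 CPM in the class named after them. C1qa, a complement component made by microglia, reached 4095 ± 459 CPM in microglia-like cells.

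E12 lies in the period when deep-layer neurons of the cortex are born, so one planned comparison set deep-layer against upper-layer neurons. It could not be run, because no cluster was named as a corticothalamic, subcerebral or subplate class. The nearest was a cluster of 151 glutamatergic neuron-like cells, picked out after its values were seen, with the deep-layer genes Bcl11b and Tbr1 among its 10 leading genes and the subcerebral layer 5 list second (mean log2 ratio of the markers 0.81) to the list of glutamatergic neurons in general (2.98). Its other leading genes were Tfap2d, Cntn2, Nrp2, Thsd7a, Kcnq3, Slc17a6, Tfap2e and Efna5, which are not on the deep-layer lists. Whether these cells are cortical deep-layer neurons was not settled. Tbr1 also led another glutamatergic neuron-like cluster (636 cells) and an intermediate progenitor-like cluster (217 cells). Naming each cell alone by its highest marker score gave 1.86% corticothalamic, 1.91% subplate and 1.65% subcerebral cells beside 2.98% upper-layer cells, while the same rule gave 1.69% ependymal and 1.61% mural cells. Unc5d, a netrin receptor, was at 288 ± 22.8 CPM in glutamatergic neuron-like cells. Among deep-layer markers, Foxp2 was at 5.89 ± 0.450 CPM in glutamatergic neuron-like cells, below its 17.7 ± 1.12 CPM in OPC-like cells, and Tle4 stood at 64.7 ± 3.92 and 68.8 ± 0.230 CPM. Fezf2, a transcription factor of subcerebral neurons, was at 17.8 ± 2.57 CPM in glutamatergic neuron-like cells and 0.789 ± 0.104 CPM in OPC-like cells, and Bcl11b at 81.3 ± 5.44 and 19.9 ± 2.21 CPM. Cplx3, a subplate marker, had 0 UMIs in glutamatergic neuron-like cells.

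Single cells thinned to 2000 UMIs gave a similar split between the lists. At least 3 upper-layer markers were seen in 31.3% of glutamatergic neuron-like cells (521 of 1667, 95% interval 29.0% to 33.5%) and in 46.1% of upper-layer neuron-like cells (47 of 102). In the reference classes they were seen in 1.18% of OPC-like (72 of 6077) and 3.14% of astroglia-like cells (106 of 3377). The same list was seen in 11.8% ± 4.33 of MGE interneuron-like and 22.1% ± 1.57 of intermediate progenitor-like cells. At least 3 corticothalamic markers were seen in 0.60% of glutamatergic neuron-like cells (10 of 1667, 0.288% to 1.10%), between the 0.0888% of astroglia-like cells (3 of 3377, 0.0183% to 0.259%) and the 1.53% of OPC-like cells (93 of 6077). OPC-like cells share genes such as Foxp2 with this list, so its background was not settled. Subplate markers gave 0 of 1667 cells, which allows up to 0.221%, against 0 of 3377 astroglia-like cells and 0.181% of OPC-like cells, the latter from replicate 2 alone (0 of 2994 and 11 of 3083). Subcerebral layer 5 markers were seen in 0.60% of glutamatergic neuron-like cells (10 of 1667) against 0.0296% of astroglia-like cells (1 of 3377, up to 0.165%) and 0 of 6077 OPC-like cells, which allows up to 0.0607%. By library the share was 0.383% in replicate 1 (3 of 784, 0.0790% to 1.11%) and 0.793% in replicate 2 (7 of 883, 0.319% to 1.63%). Only in replicate 2 did the interval clear the upper bounds of both reference classes there (0.214% and 0.120%), against 0.337% and 0.123% in replicate 1. Striatal projection neuron-like cells, which share markers such as Foxp2 and Bcl11b with these lists, had 8.59% ± 3.57 for the corticothalamic and 4.88% ± 1.67 for the layer 5 list. Without thinning, upper-layer markers were seen in 58.5% of glutamatergic neuron-like and 25.6% of OPC-like cells, at median depths of 5080 and 8223 UMIs. They were also seen in 73.4% of upper-layer neuron-like, 52.0% of astroglia-like, 65.8% of other dividing and 79.7% of intermediate progenitor-like cells. Median depths there were 5057, 9722, 16155 and 7119 UMIs. The list was therefore not specific to upper-layer neurons at full depth. By the shares of intermediate progenitor-like and MGE interneuron-like cells it was not specific after thinning either. It held 8 markers, against 7 in each deep-layer list, at the same limit of 3 markers. Thinning left out 425 and 225 shallower glutamatergic neuron-like cells in replicates 1 and 2, and 316 and 262 OPC-like cells.

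**Figure D2:**
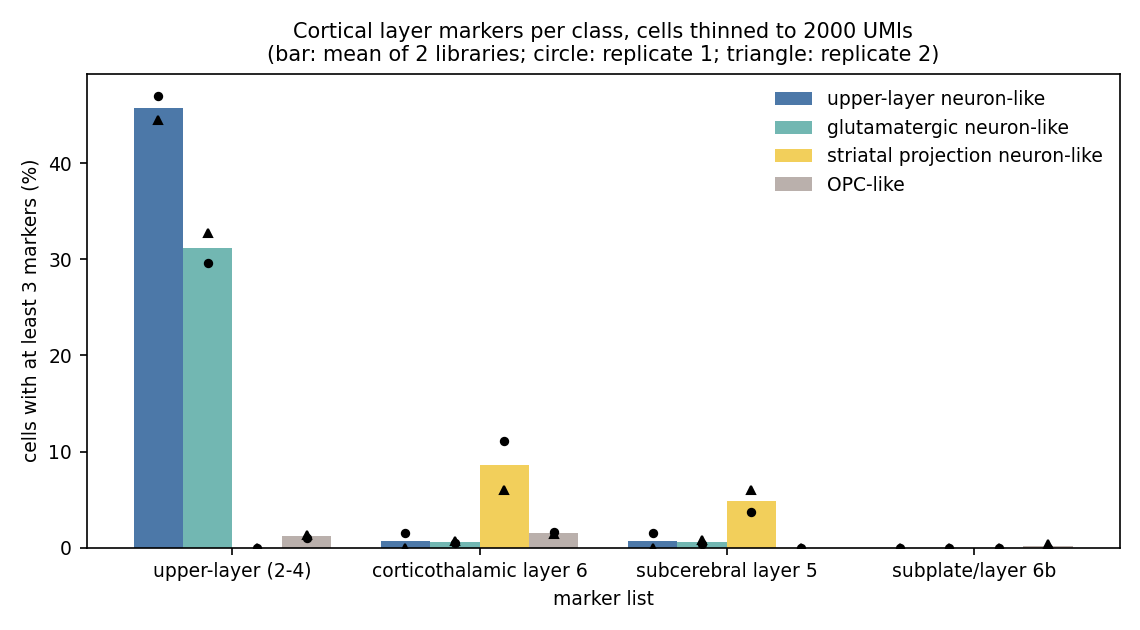
Percent of cells, each thinned to 2000 UMIs, in which at least 3 markers of a layer list were seen, for 4 lists in 4 classes. Bars are means of both libraries, circles replicate 1 and triangles replicate 2, and upper-layer markers were seen in 31.2% of glutamatergic neuron-like cells as the mean of the replicates, against 1.18% of OPC-like cells.

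In edgeR's quasi-likelihood test, 17 of 25 axon guidance genes and 15 of 23 synaptic vesicle genes were lower in GABAergic than in glutamatergic neurons, and all 18 S phase genes were higher. Without the partly dividing GABAergic neuron-like class, 7 of the 18 S phase genes were higher, with a median log2 fold change of 0.26 in place of 1.40. Olfactory bulb neuroblast-like cells were 1124 of the 1880 GABAergic cells, and no setting left them out. Cell type and maturity can therefore not be told apart in this contrast. Sema3c, a secreted guidance cue, was at 10.2 ± 5.26 CPM in GABAergic and 357 ± 44.2 CPM in glutamatergic cells (n = 2 libraries), a log2 fold change of -5.08 ± 0.10 (SE). Nrp1, a semaphorin receptor, was at 9.58 ± 1.94 and 268 ± 24.7 CPM (-4.74 ± 0.10). Slit1, a repellent ligand of Robo receptors, went the other way, with 22.9 ± 2.65 CPM in GABAergic and 3.59 ± 1.67 CPM in glutamatergic cells (2.78 ± 0.23). All genes named for this comparison had the same direction in both libraries. In mm10, Sema3c (ENSMUSG00000028780, protein-coding) lies on chromosome 5 from 17574281 to 17730268, Nrp1 (ENSMUSG00000025810, protein-coding) on chromosome 8 from 128358604 to 128503363 and Slit1 (ENSMUSG00000025020, protein-coding) on chromosome 19 from 41600257 to 41743665.

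Of 25 axon guidance genes, 3 were higher and 17 lower in GABAergic cells, with a median log2 fold change of -1.09 (camera adjusted p = 4.93e-08, and adjusted p = 0.0468 with an estimated correlation). The synaptic vesicle list had 2 higher and 15 lower members of 23 (median -0.58, camera adjusted p = 4.10e-05, adjusted p = 0.0468 with an estimated correlation). Syt4, a synaptotagmin, was lower (-2.31 ± 0.08) and Syt11 higher (0.24 ± 0.06), the latter a call lost with no replicate block. For 6 other lists the camera call was lost with an estimated correlation. Of 12 cadherins, 1 was higher and 8 lower (median -0.70, camera adjusted p = 0.00192, adjusted p = 0.0956 with an estimated correlation), with Cdh10 at -3.94 ± 0.14 and Cdh22 at 2.46 ± 0.48. Of 26 voltage-gated channel genes, 3 were higher and 15 lower, or 16 lower adjusted over the list alone (median -0.66, camera adjusted p = 0.000775, adjusted p = 0.0956 with an estimated correlation). The potassium channel gene Kcnq3 was lower (-3.89 ± 0.14) and the calcium channel subunit gene Cacna2d3 higher (2.86 ± 0.20). GABA receptors and chloride transporters had 2 higher and 8 lower of 15 (median -0.34, camera adjusted p = 0.0480, adjusted p = 0.253 with an estimated correlation), with Gabra2 at -2.40 ± 0.09 and Gabrg3 at 2.24 ± 0.38. Postsynaptic scaffold and kinase genes had 3 higher and 10 lower of 19 (median -0.30, camera adjusted p = 0.0106, adjusted p = 0.146 with an estimated correlation), with Nlgn1, a synaptic adhesion molecule, at -2.21 ± 0.12 and Camk2d, a kinase subunit, at 1.56 ± 0.16.

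All 18 S phase genes were higher in GABAergic cells (median 1.40, camera adjusted p = 2.39e-14), and the call was lost at an adjusted p = 0.0956 with an estimated correlation. Mcm2, part of the replicative helicase, was at 39.4 CPM against 5.81 CPM (2.85 ± 0.17), and Cdc6, which loads that helicase, at 3.40 ± 0.34. Beside this stands the GABAergic neuron-like class, in which 18.3% ± 1.21 of the cells thinned to 2000 UMIs showed at least 2 markers of division (45.2% unthinned, median 8550.5 UMIs), against 2.09% ± 0.0731 of OPC-like and 1.31% ± 0.610 of CGE interneuron-like cells. Without that class, a setting chosen after the data had been seen, 7 of the 18 genes were higher and 0 lower, with a median of 0.26. The unadjusted camera p was then 0.00998. Nuclear oxidative phosphorylation genes were higher for 12 of 21 and lower for 0 (median 0.20, camera adjusted p = 0.000173, adjusted p = 0.253 with an estimated correlation), with Atp5b, a subunit of ATP synthase, at 0.43 ± 0.06.

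The other 8 lists did not pass camera. Glutamate receptors had 8 higher and 6 lower of 18, or 8 and 8 adjusted over the list alone (camera adjusted p = 0.784), and their median (-0.07) and mean (0.27) differed in sign, with the test pointing down. The AMPA receptor genes Gria2 (-1.61 ± 0.06) and Gria3 (-1.88 ± 0.16) were lower, and the kainate receptor gene Grik1 (2.44 ± 0.38) was higher. Immature or migrating neuron genes had 7 higher and 3 lower of 15 (median 0.10, camera adjusted p = 0.0766), with Stmn2 at 1.05 ± 0.05 and Dpysl5 at -0.65 ± 0.05. Neurofilament and cytoskeleton genes had 5 higher and 7 lower of 15, 8 lower adjusted over the list alone (camera adjusted p = 0.285). Notch and Wnt pathway genes had 6 higher and 3 lower of 16 (camera adjusted p = 0.497), with Id4, an inhibitor of bHLH factors, at 2.10 ± 0.08 and the ligand Wnt7b at -3.42 ± 0.15. Camera adjusted p was 0.798 for p53 response genes (2 higher and 3 lower of 16), 0.435 for immediate early and dissociation stress genes (7 and 4 of 19, or 8 and 5 adjusted over the list alone), 0.383 for cholesterol synthesis (7 and 4 of 18) and 0.159 for glycolysis (3 and 8 of 18).

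Outside the lists, Mob3b was higher in GABAergic cells, at 45.5 ± 6.22 against 0.314 ± 0.195 CPM (7.15 ± 0.30), as were the transcription factor genes Zbtb16 (5.75 ± 0.29) and St18 (4.74 ± 0.20). The antisense transcript Dlx1as (5.74 ± 0.31) overlaps Dlx1, so its counts are uncertain, and so are those of Syt4, Nlgn1, Id4, Wnt7b, Unc5a and Prdm16, whose exons overlap another counted gene. Lower were Frmd6 (-4.35 ± 0.22), Lingo1 (-4.26 ± 0.15), Unc5a, a netrin receptor (-3.85 ± 0.30), and Prdm16, a transcription regulator (-3.05 ± 0.17). In the edgeR quasi-likelihood test, 4070 of 11079 genes not used for clustering were called after Benjamini-Hochberg adjustment, 2151 higher and 1919 lower, and 1055 of them changed at least 2-fold. The balance turned to 2843 higher and 2885 lower with the genes used for clustering counted, 1611 and 1723 without the GABAergic neuron-like class and 1966 and 2102 with at least 3000 UMIs, the last 2 settings being chosen after the data had been seen. For example, Slit1 had an adjusted p = 1.18e-32 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at a log2 fold change of 2.78 and higher in both libraries. Median depth and mitochondrial share were 4547.5 UMIs and 3.17% in GABAergic and 5158 UMIs and 3.68% in glutamatergic cells.

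In the same test, astroglia had lower RNA than glutamatergic neurons for 14 of 15 cytoskeleton genes and 24 of 26 voltage-gated channel genes, and higher RNA for all 18 cholesterol synthesis genes. Tubb3, a neuronal tubulin, was at 51.3 ± 1.13 CPM in astroglia and 2026 ± 107.5 CPM in glutamatergic neurons (n = 2 libraries), a log2 fold change of -5.16 ± 0.06, and Dcx, a microtubule protein of migrating neurons, at 20.9 ± 1.93 and 673 ± 112 CPM (-4.87 ± 0.07). Id3, an inhibitor of bHLH transcription factors, was at 2089 ± 75.9 and 95.3 ± 23.7 CPM (4.61 ± 0.07), and Grm3, a metabotropic glutamate receptor, at 174 ± 12.8 and 6.77 ± 0.415 CPM (4.83 ± 0.10). All genes named here had the same direction in both libraries. In mm10, Tubb3 (ENSMUSG00000062380) lies on chromosome 8 from 123411424 to 123422015, Id3 (ENSMUSG00000007872) on chromosome 4 from 136143497 to 136145755 and Grm3 (ENSMUSG00000003974) on chromosome 5 from 9485541 to 9725170, all protein-coding.

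With an estimated correlation, 5 lists kept their call. All 15 immature or migrating neuron genes were lower in astroglia (median -3.29, camera adjusted p = 9.13e-11, adjusted p = 0.0248 with an estimated correlation), as were 14 of 15 neurofilament and cytoskeleton genes, with 0 higher (median -3.58, camera adjusted p = 4.78e-08, adjusted p = 0.0145 with an estimated correlation). Voltage-gated channels had 2 higher and 24 lower of 26 (median -2.48, camera adjusted p = 6.48e-08, adjusted p = 0.0145 with an estimated correlation), with the potassium channel gene Kcna2 at 2.41 ± 0.13. Synaptic vesicle genes had 2 higher and 21 lower of 23 (median -2.54, camera adjusted p = 2.44e-07, adjusted p = 0.0145 with an estimated correlation), with Syt1, the calcium sensor of fast release, at -4.64 ± 0.14 and Syt11 at 1.81 ± 0.06. Axon guidance genes had 2 higher and 20 lower of 25 (median -2.31, camera adjusted p = 6.48e-08, adjusted p = 0.0145 with an estimated correlation), with Sema3c at -5.58 ± 0.07 and Ntn1, the guidance cue netrin, at 2.19 ± 0.33.

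The calls of 8 lists were lost with an estimated correlation. All 18 cholesterol synthesis genes were higher in astroglia (median 1.73, camera adjusted p = 3.64e-08, adjusted p = 0.0908 with an estimated correlation), with Msmo1 at 389 against 61.8 CPM (2.80 ± 0.05) and Idi1 at 2.72 ± 0.06. Notch and Wnt pathway genes were higher for 14 and lower for 1 of 16 (median 2.96, camera adjusted p = 1.02e-05, adjusted p = 0.0519 with an estimated correlation), the lower one being Wnt7b (-0.81 ± 0.07). Immediate early and dissociation stress genes had 15 higher and 2 lower of 19 (median 2.50, camera adjusted p = 1.44e-05, adjusted p = 0.0504 with an estimated correlation), with Klf4 at 144 against 8.82 CPM (4.16 ± 0.09), Atf3 at 4.15 ± 0.21 and the chaperone gene Hsp90aa1 at -0.79 ± 0.05. Oxidative phosphorylation had 20 higher, 3 of them without that direction in the CPM of both libraries, and 1 lower of 21 (median 0.32, camera adjusted p = 0.000319, adjusted p = 0.202 with an estimated correlation). Glycolysis had 13 higher and 4 lower of 18 (median 1.08, camera adjusted p = 0.00331, adjusted p = 0.0667 with an estimated correlation), with Hk2, a hexokinase, at 4.50 ± 0.19 and Eno2, the neuronal enolase, at -1.97 ± 0.25. S phase genes had 16 higher and 1 lower of 18 (median 1.13, camera adjusted p = 0.000350, adjusted p = 0.252 with an estimated correlation), with Mcm3 at 3.05 ± 0.11. Glutamate receptors had 4 higher and 12 lower of 18 (median -1.42, camera adjusted p = 0.0128, adjusted p = 0.101 with an estimated correlation), with Grm5 at 3.64 ± 0.08 and the NMDA receptor gene Grin2a at -5.78 ± 0.37. Postsynaptic genes had 3 higher and 13 lower of 19 (median -0.55, camera adjusted p = 0.00658, adjusted p = 0.0792 with an estimated correlation), with Dlg2, a scaffold protein, at -4.67 ± 0.18 and Camk2d at 3.33 ± 0.10.

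Cadherins (5 higher and 5 lower of 12, camera adjusted p = 0.405), GABA receptors and chloride transporters (5 and 9 of 15, camera adjusted p = 0.154) and p53 response genes (7 and 4 of 16, camera adjusted p = 0.949) did not pass. In the p53 list the median was 0.35, or 0.47 with genes near 0 counts set at their bound, and the mean of fitted values -0.02, or 0.10 at the bound. Cdh20 was higher (2.76 ± 0.19) and Cdh8 lower (-5.76 ± 0.23), and the GABA receptor gene Gabrg1 was higher (3.91 ± 0.15). For each list, the counts were identical adjusted over the list alone. Outside the lists, Plce1, a phospholipase (5.16 ± 0.14), Cd44, a hyaluronan receptor (4.97 ± 0.27), and Cpt1a, which brings fatty acids into mitochondria (4.91 ± 0.16), were higher. Hpca, a neuronal calcium sensor (-5.93 ± 0.22), Nyap2 (-5.75 ± 0.19) and Svop, a synaptic vesicle protein (-5.30 ± 0.19), were lower. Exons of Wnt7b, Dlg2, Cdh8, Hpca and Svop overlap another counted gene, so their counts are uncertain. In the edgeR quasi-likelihood test, 7917 of 11079 genes were called after Benjamini-Hochberg adjustment, 4219 higher and 3698 lower, of which 3543 changed at least 2-fold. The balance turned to 3119 higher and 3729 lower with classes and tests from separate parts of the UMIs, and to 3554 and 4232 with doublet calls kept. Astroglia had a median of 9722 UMIs and 2.80% mitochondrial UMIs, against 5158 UMIs and 3.68% in glutamatergic neurons.

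In MGE interneuron-like cells, 11 of 17 glutamate receptor genes were higher than in CGE interneuron-like cells by edgeR's quasi-likelihood test, and 11 of 15 genes of immature neurons were lower. Gria1, an AMPA receptor subunit, was at 487 ± 28.4 CPM in MGE and 12.1 ± 4.49 CPM in CGE interneuron-like cells (n = 2 libraries). Its log2 fold change was 5.23 ± 0.25, higher in both libraries, with an adjusted p = 1.82e-95 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gap43, a growth cone protein, stood at 586 ± 74.5 and 138 ± 5.66 CPM (1.97 ± 0.15). Tubb3 was lower in MGE interneuron-like cells, at 1206 against 2731 CPM (-1.30 ± 0.08), as were Sox4, a transcription factor of young neurons (1709 against 3499 CPM, -1.14 ± 0.08), and Id4 (54.4 against 286 CPM, -2.51 ± 0.23). All genes named here had the same direction in both libraries. In mm10, Gria1 (ENSMUSG00000020524) lies on chromosome 11 from 57011387 to 57330244, Gap43 (ENSMUSG00000047261) on chromosome 16 from 42248442 to 42340651 and Id4 (ENSMUSG00000021379) on chromosome 13 from 48261228 to 48266026, all protein-coding.

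Of 17 glutamate receptor genes, 11 were higher in MGE interneuron-like cells and 0 lower, or 13 and 0 adjusted over the list alone (median 1.46, or 1.75 with genes near 0 counts at their bound, camera adjusted p = 2.22e-15, adjusted p = 0.000126 with an estimated correlation). Grin3a, an NMDA receptor subunit, was at 3.48 ± 0.35. GABA receptors and chloride transporters had 7 higher and 0 lower of 15, or 8 and 0 adjusted over the list alone (median 0.73, camera adjusted p = 6.63e-05, adjusted p = 0.00241 with an estimated correlation), with Gabrb1 at 3.90 ± 0.56, a value that is uncertain because its exons overlap those of Gabra4 in the same list. Gabrg3 (ENSMUSG00000055026) had 29 UMIs in MGE and 0 in CGE interneuron-like cells, at least 22.6-fold higher. Voltage-gated channels had 9 higher and 0 lower of 26 (median 1.01, or 0.91 at the bound, camera adjusted p = 1.32e-05, adjusted p = 0.00798 with an estimated correlation), and the calcium channel gene Cacna1e had a ratio of 32.7 (4.97 to 1380). Synaptic vesicle genes had 7 higher and 0 lower of 23, or 9 and 0 adjusted over the list alone (median 0.55, camera adjusted p = 0.000164, adjusted p = 0.0102 with an estimated correlation). The mean of their fitted values was -0.03, or 0.63 with genes near 0 counts at their bound. Syt1 was at 467 against 78.3 CPM (2.47 ± 0.17) and Syn2, a synapsin, at 1.67 ± 0.25. Cadherins had 5 higher and 1 lower of 13, or 7 and 1 adjusted over the list alone (median 2.18, camera adjusted p = 0.00280, adjusted p = 0.0102 with an estimated correlation), with Cdh13 at 2.58 ± 0.40 and Cdh2, N-cadherin, at -0.83 ± 0.17. Postsynaptic genes had 2 higher and 0 lower of 19, or 3 and 0 adjusted over the list alone (median 0.68, camera adjusted p = 0.00143, adjusted p = 0.0222 with an estimated correlation). Immediate early and dissociation stress genes had 8 higher and 0 lower of 19 (median 0.90, camera adjusted p = 0.000105, adjusted p = 0.0356 with an estimated correlation), with the transcription factor genes Klf6 at 2.42 ± 0.29 and Klf4 at 2.11 ± 0.60. Immature or migrating neuron genes had 2 higher and 11 lower of 15, or 2 and 12 adjusted over the list alone (median -0.50, camera adjusted p = 8.08e-14, adjusted p = 0.000690 with an estimated correlation), and those higher were Gap43 and Nnat (0.31 ± 0.07).

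Cholesterol synthesis had 2 higher and 0 lower of 18, or 7 and 0 adjusted over the list alone (median 0.43, camera adjusted p = 0.0108, adjusted p = 0.304 with an estimated correlation), with Cyp51, an enzyme of the pathway, at 0.92 ± 0.24. Oxidative phosphorylation had 1 higher and 4 lower of 21 (median -0.11, camera adjusted p = 0.0173, adjusted p = 0.299 with an estimated correlation). The remaining lists did not pass camera. Axon guidance had 6 higher and 4 lower of 24 (median 0.25, camera adjusted p = 0.231), with Sema3a at 4.00 ± 0.63, Efna5 at 4.22 ± 0.62 and Slit1 at -1.80 ± 0.45. Neurofilament and cytoskeleton genes had 4 higher and 2 lower of 14, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.213). Notch and Wnt pathway genes had 2 higher, Sfrp1 and Id3, and 1 lower, Id4, of 16, or 3 and 1 adjusted over the list alone (median -0.53, or -0.21 at the bound, camera adjusted p = 0.763). The p53 list had 1 higher and 0 lower of 15 (camera adjusted p = 0.525). Glycolysis had 0 higher and 1 lower of 18 (camera adjusted p = 0.525), with a test pointing down and a median of -0.02 that became 0.06 with DESeq2 size factors. The mean of fitted values was 0.11, and with genes near 0 counts at their bound the mean was -0.11 and the median -0.12. Of 18 S phase genes, edgeR's quasi-likelihood test called 0, with 0 at an unadjusted p under 0.05 and 0 by the DESeq2 Wald test (camera adjusted p = 0.309).

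Outside the lists, several genes had few UMIs in the lower class and are given as ratios with counting intervals. Higher in MGE interneuron-like cells were Tshz3, a zinc finger transcription factor gene (58.3, interval 9.55 to 2390), Lor (49.0, 7.88 to 2030) and Syndig1 (46.7, 7.46 to 1930). Glipr2 had 0 against 30 UMIs and was at least 4.29-fold lower, Pipox had 0 against 29 and was at least 4.14-fold lower. Exons of Id4, Syn2, Cyp51 and Syndig1 also overlap another counted gene, so their counts are uncertain. In the edgeR quasi-likelihood test, 744 of 9881 genes were called after Benjamini-Hochberg adjustment, 287 higher and 457 lower. With DESeq2 size factors 348 were higher and 362 lower, which moved the higher share of calls from 38.6% to 49.0%, and with the DESeq2 Wald test 368 were higher and 333 lower. MGE interneuron-like cells were few (85 and 75 cells per library, against 164 and 144) and shallower, with medians of 2113 and 2820 UMIs against 4256.5 and 5122. Their mitochondrial share was 6.17% ± 0.498 against 3.02% ± 0.0282. Most called genes of immature neurons were lower in them too. Origin, maturity and mitochondrial share can therefore not be told apart in this contrast. At least 3 upper-layer markers of glutamatergic neurons were seen in 11.8% ± 4.33 of MGE interneuron-like cells thinned to 2000 UMIs, against 0.439% ± 0.620 of CGE interneuron-like cells. The count of calls was 343 when classes and tests came from separate parts of the UMIs, and 1268 (661 higher and 607 lower) with the genes used for clustering counted. With separate parts the calls of Cdh2, Nnat, Klf4, Cyp51 and Pipox were lost, and that of Klf4 also with doublet calls kept, with at least 1000 genes or with at least 3000 UMIs.

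**Figure D3:**
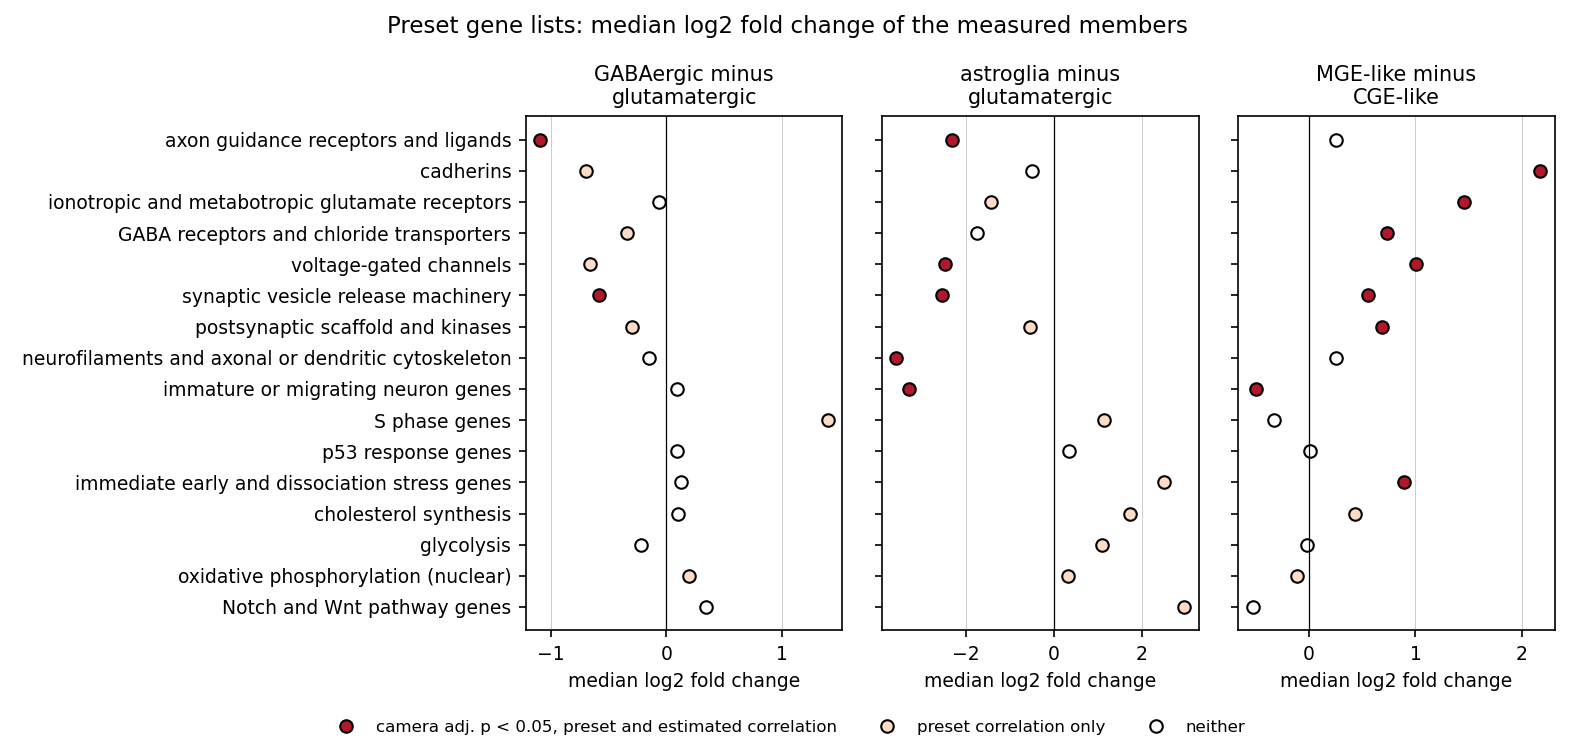
Median log2 fold change of each of 16 gene lists in the 3 planned contrasts that were run, with dark red for lists called by camera with both the preset and the estimated correlation, light red for the preset correlation alone and white for neither. S phase genes stand highest in GABAergic against glutamatergic cells (1.40), and immature neuron genes stand far below 0 in astroglia (-3.29).

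The libraries themselves were compared over all kept cells. Pearson's r of log2 CPM was 0.997 across 14125 genes with at least 1 CPM, where genes are not independent replicates. Chi-square per degree of freedom was 23.5 over 14879 genes, above UMI counting noise, which separate draws of cells from 1 pool would also exceed. Only 62 barcodes (0.447% of replicate 1) were shared. Of 3767 genes with at least 50 CPM in either library, 3 differed at least 2-fold. S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721, mm10) and S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), which encode the subunits of a protein of neutrophils and other myeloid cells, were lower in replicate 1. S100a9 was at 1.84 against 61.7 CPM and S100a8 at 8.84 against 69.9 CPM. The histone gene Hist1h4d was at 83.3 against 40.3 CPM, which is uncertain because histone genes share near-identical copies. Thinning each cell to 2000 UMIs left 1 gene with such a ratio, and equal class shares left 2.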

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

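The shares of barcodes over the mitochondrial limit and the tests of deep-layer neurons were chosen after the results had been seen. Barcodes with over 10% mitochondrial UMIs were outside the comparisons. When they were clustered with the rest, upper-layer neuron-like cells made up 5.71% of those barcodes in replicate 1 and 4.53% in replicate 2, against 0.530% ± 0.206 of the kept cells (SD, n = 2). The last share came from the main clustering, not the joint one. Among the kept cells this class had the highest median mitochondrial share of the classes, 6.95%, so the limit cuts into it more readily. No control samples exist to set beside these values.

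A pattern weighed here is that no deep-layer neuron class was found among cells sorted for EdU after dating at E12. The sort also held dividing OPC-like (4.96%), dividing GABAergic (3.72%) and other dividing cells (4.41%), so not all sorted cells had left division at E12. At resolution 2.0, 0 of 38 clusters were led by a deep-layer list. No cluster was led by the upper-layer list either, and the general glutamatergic list led the glutamatergic clusters. That count can therefore not decide whether deep-layer cells were present. Naming each cell alone gave 1.86% corticothalamic, 1.91% subplate and 1.65% subcerebral cells, close to the 1.69% ependymal and 1.61% mural cells of the same rule. For loss to the mitochondrial limit, at most 0.0992% of the removed glutamatergic or upper-layer neuron-like barcodes, thinned to 1000 UMIs, had 3 or more markers of a deep-layer list (1 of 1008, 95% interval 0.00251% to 0.551%), against 0.0842% of kept cells of these classes thinned alike (2 of 2374, 0.0102% to 0.304%), which is too few to decide. A merger of corticothalamic neurons into the glutamatergic neuron-like class also stays open, since 0.60% of these cells had 3 markers, above astroglia-like (0.0888%) and below OPC-like cells (1.53%), and for subplate neurons 0% (0 of 1667, up to 0.221%) sets a limit only. For subcerebral layer 5 neurons the share of 0.60% came from 0.383% in replicate 1 (0.0790% to 1.11%) and 0.793% in replicate 2 (0.319% to 1.63%) and cleared the upper bounds of both reference classes in replicate 2 alone, so a merger stays open there too. The sort for the brightest EdU, the survival of neurons during dissociation and the course of labelling were not tested, and the design holds no group that would test a biological explanation.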

How the results depend on the processing

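Of the alternatives, those chosen after the data had been seen were cells of at least 3000 UMIs, no mitochondrial limit, dividing GABAergic cells counted as GABAergic, GABAergic cells without the GABAergic neuron-like class, and the whole contrast of OPC-like against astroglia-like cells. No named gene changed direction. The contrast of deep-layer against upper-layer neurons and its alternatives were not run. Genes called in GABAergic against glutamatergic cells (4070) ranged from 2956 with separate parts of the UMIs for classes and tests to 5736 with dividing cells included, in astroglia against glutamatergic cells (7917) from 6848 to 10703, and in OPC-like against astroglia-like cells (6961) from 5520 to 9479, all within 1.5 times. In MGE against CGE interneuron-like cells (744) the count fell to 343 with separate parts of the UMIs, a setting that both leaves fewer UMIs for each test and rebuilds the classes (87.8% of cells kept their class), the part of each in the fall not being tested, and rose to 1268 with the genes used for clustering counted, the latter because more genes were counted, and otherwise lay between 617 and 956. The balance of higher and lower calls turned under some settings: in astroglia against glutamatergic cells from 4219 and 3698 to 3119 and 3729 with separate parts and to 3554 and 4232 with doublet calls kept, in GABAergic against glutamatergic cells from 2151 and 1919 to 2843 and 2885 with clustering genes counted, 1611 and 1723 without the GABAergic neuron-like class and 1966 and 2102 at 3000 UMIs. In MGE against CGE interneuron-like cells it turned from 287 and 457 to 368 and 333 with the DESeq2 Wald test and to 661 and 607 with clustering genes counted. In OPC-like against astroglia-like cells it turned from 3447 and 3514 to 4774 and 4705 with clustering genes counted and to 3606 and 3533 at 3000 UMIs. The glycolysis median of the MGE contrast changed sign with DESeq2 size factors (-0.02 to 0.06). With no replicate block the counts were 3183, 7342, 665 and 5520. A library block pairs classes of the same library by design, and of the named genes 1, Syt11 in GABAergic against glutamatergic cells (0.24), lost its call without it. With an estimated correlation the lists called fell from 8 to 2, from 13 to 5, from 10 to 8 and from 11 to 8 in these 4 contrasts. The genes differing 2-fold between libraries were 3, 1 after thinning to 2000 UMIs and 2 with equal class shares.

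Class shares moved by more than the SD between libraries under several settings, and the cause was not tested. With at least 1000 genes per cell the GABAergic, astroglial, glutamatergic and oligodendrocyte lineage shares were 8.04%, 19.8%, 10.2% and 39.7%. With at most 5% mitochondrial UMIs they were 8.41%, 21.5%, 10.3% and 40.7%, and with at least 3000 UMIs 7.50%, 21.1%, 9.59% and 40.6%. Keeping doublet calls gave 8.51% GABAergic, 19.1% astroglial and 10.8% glutamatergic cells. Leiden resolution 0.5 gave 20.2% astroglia, and no mitochondrial limit gave 12.7% astroglia, 13.6% glutamatergic cells and 36.2% oligodendrocyte lineage, so that astroglia then stood below glutamatergic cells. Naming each cell alone gave 14.1% GABAergic, 19.8% glutamatergic and 27.9% oligodendrocyte lineage cells, with glutamatergic cells above astroglia (16.9%). There several lists were summed for each neuron family and a single list was used for astroglia. The main astroglial share leaves out the unnamed cluster of 1290 cells with astroglial markers, so its order beside glutamatergic cells depends on naming too. Over the settings the smaller families ranged from 0% to 4.34% (dividing GABAergic), 3.63% to 9.90% (other dividing), 1.00% to 2.54% (intermediate progenitors), 0.762% to 1.36% (Cajal-Retzius), 1.19% to 1.85% (microglia and macrophages), 0.0897% to 2.95% (vascular and fibroblast) and 3.00% to 18.1% (unnamed). Per-cell naming has no dividing GABAergic class, which gives the 0%, and gave the highest values of the other dividing and the vascular cells. Leaving out each library in turn gave values with no test, since 1 library leaves no spread: 8.83% to 9.49% GABAergic, 16.1% to 17.1% astroglial, 11.6% to 12.6% glutamatergic and 37.4% to 39.0% oligodendrocyte lineage cells. Of the values of named genes under the alternatives, 1186 of the planned ones kept direction and side of the threshold and 9 lost the call, and of the added ones 650 kept and 3 lost it, and 5 values could not be computed. Of the lost calls, 5 came with separate parts of the UMIs. At 3000 UMIs the interneuron contrast rested on 23 and 36 MGE interneuron-like cells.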

Other observations

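The contrast of OPC-like against astroglia-like cells, the counts of S100a8 and S100a9 per cell, the test of shallower sampling and the test of the MHC class II source were chosen after the results had been seen. Between OPC-like and astroglia-like cells, the main glial classes here, 25 of 26 voltage-gated channel genes were higher and 14 of 16 Notch and Wnt pathway genes lower in OPC-like cells by edgeR's quasi-likelihood test. Scn1a, a sodium channel gene, was at 25.4 ± 2.00 CPM in OPC-like and 0.720 ± 0.0734 CPM in astroglia-like cells (SD, n = 2), a log2 fold change of 4.92 ± 0.18 (SE), and Scn3a at 86.6 against 3.14 CPM (4.62 ± 0.09). Id1, an inhibitor of bHLH factors, was lower in OPC-like cells (-4.27 ± 0.04), as was the Wnt effector Lef1 (-4.32 ± 0.18), while the Notch ligand Dll1 was higher (2.56 ± 0.09). All genes named for this contrast had the same direction in both libraries. In mm10, Scn1a (ENSMUSG00000064329, protein-coding) lies on chromosome 2 from 66270778 to 66440840. Some called members of the lists lacked that agreement, among them 3 oxidative phosphorylation genes and 1 of the 2 lower immature neuron genes. In edgeR's quasi-likelihood test 6961 of 9881 genes were called after Benjamini-Hochberg adjustment, 3447 higher and 3514 lower. That balance turned to 4774 higher and 4705 lower with the genes used for clustering counted, and to 3606 and 3533 with at least 3000 UMIs. The lead of lower calls widened to 3035 and 3850 with doublet calls kept, and to 3622 and 4357 with no filter on low counts. Median depth and mitochondrial share were 8223 UMIs and 3.25% in OPC-like against 9722 UMIs and 2.80% in astroglia-like cells. The OPC-like class holds a cluster of low UMI count (1359 of 6655 cells), while its astroglial counterpart (1290 cells) stayed unnamed and outside the contrast.

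Voltage-gated channels were higher in OPC-like cells for 25 of 26 genes and lower for 0 (median 2.22, camera adjusted p = 4.82e-08, adjusted p = 0.00597 with an estimated correlation). Neurofilament and cytoskeleton genes had 13 higher and 1 lower of 14 (median 2.06, camera adjusted p = 1.33e-06, adjusted p = 0.00597 with an estimated correlation), with Ina, an internexin, at 4.18 ± 0.07 and Nefl, neurofilament light chain, at 4.19 ± 0.21. Synaptic vesicle genes had 17 higher and 3 lower of 23 (median 0.98, camera adjusted p = 0.000167, adjusted p = 0.00597 with an estimated correlation), with Snap25 at 3.07 ± 0.08. Glutamate receptors had 12 higher and 3 lower of 17, or 13 and 3 adjusted over the list alone (median 1.22, camera adjusted p = 0.00522, adjusted p = 0.0486 with an estimated correlation), with Grik1 at 3.41 ± 0.14 and Grm3 at -4.71 ± 0.06. Postsynaptic genes had 12 higher and 3 lower of 19 (median 0.52, camera adjusted p = 0.0121, adjusted p = 0.0486 with an estimated correlation), and immature neuron genes 12 higher and 2 lower of 15 (median 0.75, camera adjusted p = 0.000328, adjusted p = 0.0486 with an estimated correlation), with Dcx at 2.80 ± 0.07.

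Lower in OPC-like cells were 14 of 16 Notch and Wnt pathway genes, with 1 higher (median -1.49, camera adjusted p = 1.26e-06, adjusted p = 0.00597 with an estimated correlation), and 16 of 19 immediate early and dissociation stress genes, with 2 higher (median -1.65, camera adjusted p = 2.40e-07, adjusted p = 0.0103 with an estimated correlation), among them Zfp36 (-4.06 ± 0.08) and Atf3 (-3.68 ± 0.12). Cholesterol synthesis had 1 higher and 16 lower of 18 (median -0.46, camera adjusted p = 0.000160, adjusted p = 0.0989 with an estimated correlation), with Mvk at -1.03 ± 0.04. Glycolysis had 5 higher and 13 lower of 18 (median -0.72, camera adjusted p = 0.00528, adjusted p = 0.0847 with an estimated correlation), with Hk2 at -2.50 ± 0.09 and Pfkp at 1.74 ± 0.09. Oxidative phosphorylation had 1 higher and 16 lower of 21 (median -0.22, camera adjusted p = 0.00522, adjusted p = 0.160 with an estimated correlation). Not called were axon guidance (10 higher and 10 lower of 24, median -0.08, mean -0.05, test pointing up, camera adjusted p = 0.691), cadherins (6 and 5 of 13, or 7 and 5 adjusted over the list alone, camera adjusted p = 0.587), GABA receptors (9 and 6 of 15, camera adjusted p = 0.427), S phase genes (3 and 8 of 18, camera adjusted p = 0.334) and p53 response genes (5 and 6 of 15, median -0.14, mean 0.11, test pointing up, camera adjusted p = 0.691). Outside the lists, Slc22a3, an organic cation transporter (5.81 ± 0.20), and Pllp, a myelin protein (4.80 ± 0.07), were higher, and Ttyh2 (-5.68 ± 0.19), Cd44 (-4.99 ± 0.17) and Hspb8 (-4.93 ± 0.15) lower. Exons of Lef1, Ina, Nefl, Zfp36, Pfkp, Slc22a3 and Pllp overlap another counted gene, so their counts are uncertain.

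The difference in S100a8 and S100a9 between the libraries rested on few cells. In replicate 2, 11623 of the 11735 UMIs of both genes lay in 6 cells, 5 of them microglia-like, and in replicate 1, 791 of 847 UMIs lay in 3 microglia-like cells. That name comes from the main clustering. At resolution 2.0 a cluster of 16 cells was led by the list of other immune cells, which holds S100a8 and S100a9. Whether the cells with these UMIs lie in it was not checked, so they need not be microglia.

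A further pattern is that OPC-like, astroglial (by markers, the cluster stayed unnamed) and glutamatergic cells each had a cluster of low UMI count, with medians of 2132, 1984 and 2094 UMIs against 9016, 9964 and 5964 in the deeper clusters set beside them. Deeper astroglial cells were a cluster of 1529 of the 3398 astroglia-like cells, and deeper glutamatergic cells 1379 of the 2317 glutamatergic neuron-like cells. Over both libraries, Malat1 was at 71143 CPM in the low astroglial cluster and at 14068 to 36093 CPM in the astroglia-like clusters. Shallower sampling of otherwise equal cells is argued against in OPC-like and astroglial cells, where the share of Malat1, a nuclear RNA, was higher in the low clusters by a log2 ratio of at least 1.23 ± 0.04 (SD, n = 2). Damaged cells that lost cytoplasmic RNA may account for these clusters, since summed ribosomal protein mRNAs were lower by a log2 ratio of -0.584 or beyond (-0.58 ± 0.01 in astroglial, -1.12 ± 0.01 in OPC-like cells). These mRNAs were not compared with the other astroglia-like clusters. In the glutamatergic cluster that explanation is argued against, with ribosomal protein mRNAs at a log2 ratio of 0.114 ± 0.04 and Malat1 at -0.34 ± 0.03. No biological explanation was tested.

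MHC class II genes, whose products present antigen, were seen in 1 astroglia-like cluster of 589 cells, which was found through these genes. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419, mm10, protein-coding) was there at 112 ± 1.06 CPM, with a UMI in 32.5% of cells, against 2.58 ± 0.134 CPM in other astroglia-like cells, 4.07 CPM and 3.03% in OPC-like cells and 9.09 CPM and 9.48% in microglia-like cells, at median depths of 8492, 10047, 8223 and 13801 UMIs. RNA from microglia or macrophages, free or in doublets, is argued against as the source, because H2-Ab1 stood 12.4-fold above its level in microglia-like cells (11.6 and 13.2 by library), and RNA mixed in cannot exceed its level in the source. C1qa, C1qb, C1qc, Ctss and Tyrobp summed to 4.60 CPM, against 4.64 CPM in other astroglia-like cells, while the cluster had Gfap at 498 ± 58.8 and Serpinf1 at 448 ± 14.2 CPM. Other immune cells were not tested as a source, and no biological explanation was tested.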
